A study of Mus musculus with 8 samples.

How the data were processed

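The data are 8 liver libraries, 4 PiZ and 4 PiZ/Chop-/-, each from 6-week-old male C57BL/6 mice per the labels. Per the labels' protocols, libraries were made from total RNA with the QuantSeq 3' mRNA kit and sequenced from one end with reads of 75 bases. The deposited values are raw counts per gene, not normalized, per the file headers. STAR, HTSeq and the build mm10 are named in the submitters' processing notes, with no versions; the annotation, the strand setting, the treatment of reads with several matches and any removal of duplicates are not given in the sources used here. The kit reads transcripts at the 3' end, so no correction for gene length was made. Groups and replicate numbers were taken from the sample titles. The wild-type group named in the design text was not analysed here.

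Each file held 52551 rows, 52550 mouse Ensembl gene IDs and 1 row named SERPINA1. Symbols and positions came from GENCODE mouse release M21, an annotation of mm10, in which 52403 of the IDs were found. It may not be the release the authors used. Total counts per library were 1650260, 2108457, 3064385 and 1937449 in PiZ libraries 1 to 4 and 2375907, 1850275, 2020326 and 2115661 in PiZ/Chop-/- libraries 1 to 4. The mitochondrial genes mt-Co2, mt-Atp6 and mt-Atp8 had 0 counts in every library, and mt-Co3 and mt-Nd3 had 1 and 2 counts in all. Of the 13 genes of the mitochondrial list, 7 had enough counts to be tested. Whether PCR copies were told apart is not given in the sources used here, so the depth sets a limit for counting error only. Reads of near-identical genes (Serpina1, Mup, Cyp2c, Cyp3a and Gstm families) may have been shared or dropped.

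Genes were tested with edgeR 4.0.16 in R 4.3.3. filterByExpr by group (minimum count 10) kept 8669 genes, library sizes were scaled by TMM, and the quasi-likelihood fit (glmQLFit, robust) was tested with glmQLFTest for PiZ/Chop-/- against PiZ with no covariate. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes. Ddit3, SERPINA1 and Mars also had an exact two-sided permutation test of mean log2 CPM over the 70 assignments of 4 of the 8 libraries.

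Gene lists, 40 in number, were fixed before the data were examined, with Ddit3 in none of them. They cover ER stress, inflammation, metabolism, sex-biased and zonated hepatocyte genes, and markers of other liver cell types, pancreas, fat and muscle. The last 2 lists, pancreas and adipose tissue with muscle, had under 3 tested members and were not tested, so adjustment ran over 38 lists. They were tested with camera (limma 3.58.1, two-sided) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Calls near Ddit3 were counted within 10 Mb and compared with the rest by Fisher's exact test.

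The named genes followed a rule fixed before the data were examined. It took Ddit3; the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 3 and groups that did not overlap, leaving out unnamed gene models and pseudogenes; in each list past camera or with at least 2 genes past the genome-wide threshold, up to 4 such genes by lowest p (or, in a list past camera with none, the 2 of lowest p, as values), and in any other list up to 2; and, whatever their outcome, Serpina1a to Serpina1e, Jun, Atf4, Hspa5, Trib3, Chac1, Cebpb, Rgs16, Xist, Ddx3y and Nnt. Examples in the text could be fewer. SERPINA1, Mars, Cd63 and Gpx2 were chosen after their values were seen.

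The test was checked on simulated counts, drawn from the real means, library sizes and dispersions of the 8669 genes, with 200 genes changed in each of 5 runs. It recovered 34.2% of 2-fold and 85.4% of 4-fold changes, none in the wrong direction, and 6.12% of all calls were false. A list moved 1.3-fold passed camera in 5 of 5 runs with the preset and in 5 of 5 with an estimated correlation, and 2 lists that were not moved passed with the preset over the 5 runs. The simulation drew genes independently of each other.

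Alternatives fixed before the data were examined were other scalings (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, no filter or a filter of 5 CPM in 4 libraries, a fit that was not robust, the 20 most abundant genes left out, a block of the replicate number, 1 surrogate variable (sva 3.50.0), a test against a 1.2-fold change, an adjusted p of 0.01, and each library left out in turn. DESeq2 was given the counts without the expression filter. The lists were also run with a prior count of 0.5. The omission of PiZ libraries 1 and 4 was added after seeing the data. So was that of Gm42418, which collects ribosomal RNA reads, with the mitochondrial genes. PiZ libraries 1 and 4 had the lowest mean correlations with their own group (0.931 and 0.914). That of PiZ library 1 lay close to the next, 0.932 in PiZ/Chop-/- library 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.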

Results

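Gene expression was measured in livers of 6-week-old male C57BL/6 mice by QuantSeq, a method that reads the 3' ends of messenger RNAs. Both groups carried PiZ, a transgene for the human Z variant of alpha-1 antitrypsin, which misfolds and collects in the endoplasmic reticulum (ER) of hepatocytes. In the PiZ/Chop-/- group Chop, the gene Ddit3, was deleted as well. Ddit3 encodes CHOP, a transcription factor made during ER stress. Each group had 4 libraries. The study's design text also names a wild-type group, which was not analysed here. The comparison asks which liver transcripts differ when CHOP is missing from PiZ mice. Total counts ran from 1650260 (PiZ library 1) to 3064385 (PiZ library 3) per library, and 8669 genes had enough counts to be tested. The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these libraries. Fold changes are PiZ/Chop-/- over PiZ on the log2 scale, with SE, and levels are CPM (read counts scaled to the size of each library) as mean ± SD with n = 4 per group.

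Ddit3 (ENSMUSG00000025408) was 48.5-fold lower in PiZ/Chop-/- livers. It stood at 152 ± 50.5 CPM in PiZ and at 3.03 ± 1.13 CPM in PiZ/Chop-/- (SD, n = 4 each). The raw counts were 311, 290, 595 and 180 in the PiZ libraries and 8, 3, 5 and 9 in the PiZ/Chop-/- libraries, so the level followed the label in all 8. The log2 fold change was -5.60 (SE 0.34, adjusted p = 2.35e-07, edgeR), and the exact two-sided permutation p of 0.0286 was the smallest that 4 against 4 can give. Ddit3 lies on the plus strand of chromosome 10 at 127290774 to 127296288 (mm10). Which part of it was deleted is not given in the sources used here, and the reads come from its 3' end.

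Human SERPINA1, the transgene, was also lower without CHOP, while none of the mouse paralogs passed the test. SERPINA1 stood at 1451 ± 374 CPM in PiZ and at 620 ± 70.9 CPM in PiZ/Chop-/- (SD, n = 4 each), a log2 fold change of -1.23 (SE 0.22, adjusted p = 0.00873, edgeR; exact two-sided permutation p = 0.0286). Every PiZ library was above every PiZ/Chop-/- library. SERPINA1 was chosen after its values were seen. Its call was lost without PiZ/Chop-/- library 3 (adjusted p = 0.0575) and held in the other leave-one-out fits. The 5 mouse paralogs all had positive fold changes: 0.63 for Serpina1a, 0.22 for Serpina1b, 0.72 for Serpina1c, 0.37 for Serpina1d and 1.09 for Serpina1e, with adjusted p between 0.217 and 0.712. As a list fixed before the data were examined they passed the camera set test (adjusted p = 0.00506), but not with an estimated correlation (adjusted p = 0.356), and 1 of the 5 passed when adjusted over the list alone. Serpina1c passed the genome-wide test without PiZ library 4 (log2 fold change 1.16, adjusted p = 0.00412) and without PiZ libraries 1 and 4 together (1.09, adjusted p = 0.0156). The paralogs are near-identical, so how reads were split among them is uncertain.

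**Figure D1:**
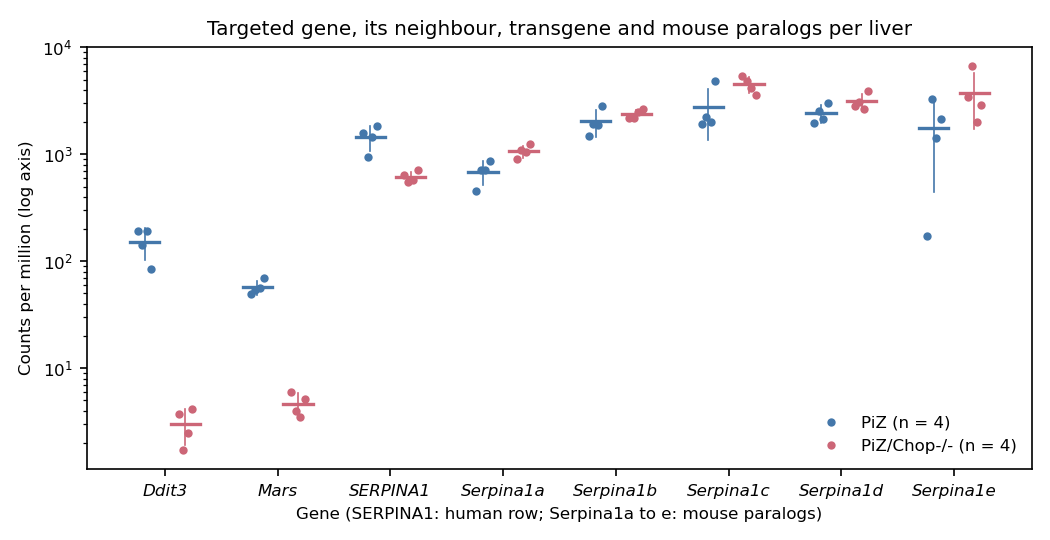
CPM (log axis) for Ddit3, its neighbour Mars, human SERPINA1 and the mouse Serpina1 paralogs in each liver library, 4 PiZ and 4 PiZ/Chop-/-. Horizontal bars mark the mean and vertical lines the SD. Ddit3 (152 against 3.03 CPM), Mars (57.4 against 4.67 CPM) and SERPINA1 (1451 against 620 CPM) were lower in every PiZ/Chop-/- library than in any PiZ library.

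In all, 89 of the 8669 genes changed between the groups, 60 of them lower and 29 higher in PiZ/Chop-/- livers (edgeR, Benjamini-Hochberg adjusted p below 0.05). The falls were the larger changes: 26 of the lower genes and 3 of the higher genes differed at least 4-fold. The groups did not overlap in 87 of the 89, which were picked for their difference in these same libraries, so this adds no support. Over all tested genes the share was 7.88%, against 2.86% expected by chance for a single gene. Genes that move together within libraries can shift this share, which was not tested. The number called moved when libraries were left out, which also leaves fewer libraries per fit. It was 81, 63, 53 and 115 without PiZ libraries 1, 2, 3 and 4. It was 49, 169, 46 and 51 without PiZ/Chop-/- libraries 1, 2, 3 and 4. Without PiZ libraries 1 and 4 together, which had the lowest mean correlations with the rest of their group (0.931 and 0.914), it was 113. Genes lower came to 35 without PiZ library 3 and to 37, 102, 32 and 37 without PiZ/Chop-/- libraries 1 to 4. Genes higher came to 18 and 54 without PiZ library 3 or 4 and to 12, 67, 14 and 14 without PiZ/Chop-/- libraries 1 to 4. In the self-test, which simulated this comparison on 8669 genes, 34.2% of 2-fold and 85.4% of 4-fold changes were recovered, so changes of these sizes can be missed with these libraries.

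After Ddit3, the deepest falls among the genes named by the rule fixed before the data were examined included enzymes, a transporter and a fetal liver protein. Ggt1, which breaks down extracellular glutathione, fell from 101 ± 19.5 to 2.98 ± 2.32 CPM (SD, n = 4 each; log2 fold change -5.02, SE 0.42, adjusted p = 1.61e-05). Abcc4, an export pump of bile acids and other organic anions, fell from 83.4 ± 25.4 to 4.04 ± 0.84 CPM (-4.33, SE 0.30, adjusted p = 5.03e-07). Ly6d, a surface protein (-4.66, SE 0.32), and Afp, alpha-fetoprotein of the fetal liver (-4.09, SE 0.48), fell with adjusted p of 5.03e-07 and 0.000243. Cbr3, a carbonyl reductase (-3.95, SE 0.36), and Nupr1, a stress-response nuclear protein (-3.94, SE 0.39), fell with adjusted p of 1.53e-05 and 0.000243. Gpx2, a glutathione peroxidase chosen after its values were seen, fell as well (-3.85, SE 0.34, adjusted p = 1.04e-05). Rap1gap2 fell too (-4.41, SE 0.85, adjusted p = 0.0357). The Rap1gap2 call was lost without PiZ library 1 or 3 (adjusted p = 0.0551 and 0.0649) and without PiZ/Chop-/- library 1, 3 or 4 (adjusted p = 0.167, 0.148 and 0.106). Its log2 fold change was -3.62 without PiZ library 4, -5.74 without PiZ/Chop-/- library 2 and -3.45 without PiZ libraries 1 and 4, where that of Afp was -3.43.

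The largest rise among the 29 genes higher was that of Hsd3b5, a male-specific steroid dehydrogenase of mouse liver, from 5.75 ± 3.59 to 46.0 ± 18.7 CPM (SD, n = 4 each; log2 fold change 2.96, SE 0.43, adjusted p = 0.00353). Cyp2c38, a cytochrome P450, rose by 2.31 (SE 0.39, adjusted p = 0.00545) and Nxpe2 by 2.22 (SE 0.37, adjusted p = 0.00571). C9, the last component of the complement attack complex, rose by 1.57 (SE 0.27, adjusted p = 0.00700), and Arid5b, a chromatin regulator, by 1.47 (SE 0.26, adjusted p = 0.00859). Car3, an abundant carbonic anhydrase, rose from 2187 ± 818 to 5931 ± 1321 CPM (log2 fold change 1.44), a call lost without PiZ library 3 (adjusted p = 0.0710) or PiZ/Chop-/- library 1 (0.0734). Clec2h (1.62) and Gprin3 (1.39) passed with all 8 libraries at adjusted p of 0.0447 and 0.0417. Clec2h was lost without PiZ library 1 or 3 (0.0894 and 0.146) and without PiZ/Chop-/- library 1, 3 or 4 (0.178, 0.139 and 0.108). Gprin3 was lost without PiZ library 1, 2 or 3 (0.103, 0.0620 and 0.0601) and without PiZ/Chop-/- library 1, 3 or 4 (0.138, 0.148 and 0.124). With limma-voom Clec2h and Gprin3 missed the threshold too (adjusted p = 0.0748 and 0.0779).

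**Figure D2:**
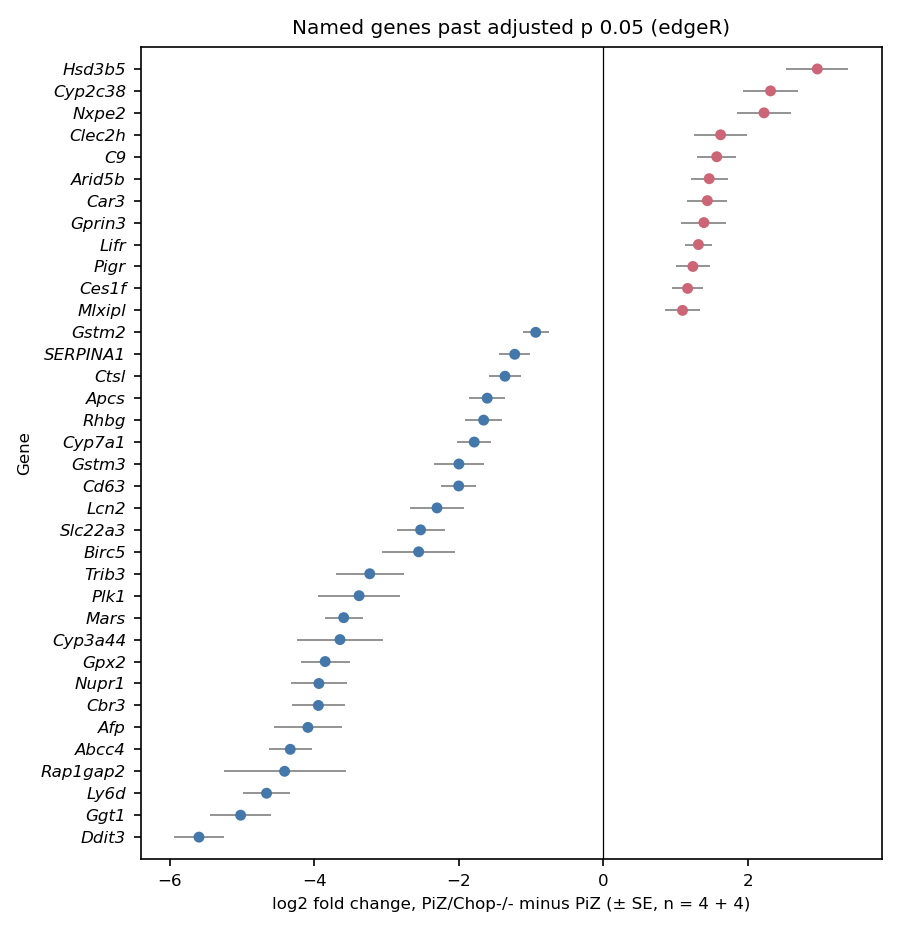
Log2 fold change, PiZ/Chop-/- minus PiZ, with its SE (horizontal axis) for the named genes past an adjusted p of 0.05 (vertical axis), from n = 4 libraries per group. Ddit3 (-5.60) and Ggt1 (-5.02) fell the most and Hsd3b5 (2.96) rose the most.

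Among 40 gene lists fixed before the data were examined, 38 had at least 3 tested members, and 19 passed the camera set test with a preset correlation of 0.01, 13 lower and 6 higher. With a correlation estimated from these libraries none of the 38 passed, the lowest adjusted p being 0.244, so each list below carries that p as well. Splits of the 8 libraries with 2 of each group on either side passed up to 10 lists with the preset. A pass with the preset is thus weak evidence alone. By fry, which asks whether a set's genes move one way on balance, cell cycle (adjusted p = 0.0240), secreted hepatocyte proteins and hepatocyte transcription factors (0.0478 each) passed.

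ER-stress and protein-folding lists were lower in PiZ/Chop-/- livers. Of 18 targets of the integrated stress response, from which Ddit3 itself was left out, 2 fell past the genome-wide threshold, none rose, and 14 of the 18 fold changes were below 0 (median -0.40, camera adjusted p = 0.000559; adjusted p = 0.323 with an estimated correlation). These 2 were Nupr1 and Trib3, a pseudokinase that CHOP induces; 3 passed when adjusted over the list alone. Trib3 fell from 217 ± 124 to 22.9 ± 11.8 CPM (SD, n = 4 each; log2 fold change -3.23, SE 0.47, adjusted p = 0.0139), a call lost without PiZ/Chop-/- library 3 (adjusted p = 0.0578) or 4 (0.0683). Of 28 ER chaperones and folding enzymes none passed singly, genome-wide or adjusted over the list alone, and 25 were below 0 (median -0.35, adjusted p = 0.000574; adjusted p = 0.421 with an estimated correlation). A list's score in a library is the median over its members of log2 CPM, each gene centred over the 8 libraries. For these 2 lists PiZ/Chop-/- library 2 scored 0.16 and 0.22. The other libraries of its group scored -0.58 to -0.19 and -0.37 to -0.30. Fkbp11 had -0.90 (adjusted p = 0.137) and Xbp1, a transcription factor of the unfolded protein response, 0.63 (adjusted p = 0.189). Both lists missed the threshold without PiZ libraries 1 and 4 (medians -0.16 and -0.17, adjusted p = 0.0862 and 0.0826), and the chaperone median was -0.21 without PiZ library 4. Of 31 genes of ER-associated degradation and translocation none passed genome-wide, 1 passed when adjusted over the list alone and 27 were below 0. The median was -0.28 (camera adjusted p = 0.000574, and 0.338 with an estimated correlation), with Derl1 at -0.83 (adjusted p = 0.0861) and Ube2g2 at -1.05 (0.165). For this list too PiZ/Chop-/- library 2 stood apart, with a score of 0.12 against -0.34 to -0.11 in the other libraries of its group.

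Other genes of the study's question did not pass. Hspa5, the ER chaperone BiP, stood at 6185 ± 1217 CPM in PiZ and 3066 ± 1817 CPM in PiZ/Chop-/- (SD, n = 4 each; log2 fold change -1.01, SE 0.33, adjusted p = 0.206, edgeR). Atf4, which lies upstream of Ddit3, had -0.42 (SE 0.42, adjusted p = 0.730). Without PiZ/Chop-/- library 2 both passed, Hspa5 at -1.50 (adjusted p = 0.00686) and Atf4 at -1.10 (adjusted p = 0.0143), and Hspa5 did with no filter on low counts (adjusted p = 0.000255). Jun had 1.05 (SE 0.80, adjusted p = 0.634) and -0.097 without PiZ/Chop-/- library 2, while Cebpb had 0.0048 (SE 0.45) and Rgs16 0.67 (SE 1.01). The sign of the Cebpb value turned with library size as the only scaling (-0.088) and without PiZ library 1 or 2 (-0.24 and -0.049) or PiZ/Chop-/- library 2 (-0.42), and that of Rgs16 without PiZ/Chop-/- library 3 (-0.014). Chac1 had too few counts to be tested.

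Lists of protein synthesis and turnover were lower as well. Of 53 ribosomal protein genes 48 were below 0 (median -0.34, adjusted p = 4.99e-05; adjusted p = 0.323 with an estimated correlation), with Rpl13a at -0.71 (adjusted p above the threshold). Of 34 proteasome and heat shock genes 26 were below 0 (median -0.28, adjusted p = 0.00201; adjusted p = 0.338 with an estimated correlation), with Psmb5 at -0.94 (adjusted p = 0.0788) and Psmb4 at -0.81 (0.102). Of 19 cytosolic aminoacyl-tRNA synthetases 18 were below 0 (median -0.19, adjusted p = 0.00256; adjusted p = 0.356 with an estimated correlation), with Rars at -0.86 (adjusted p = 0.116) and Sars at -0.57 (0.253). PiZ/Chop-/- library 2 scored 0.10 for the proteasome list, against -0.19 to -0.16 in the other libraries of its group. For the synthetases it scored 0.20, against -0.39 to -0.18. Its ribosomal score of -0.13 lay within those of the others (-0.25 to -0.054). The synthetase median was -0.57 without PiZ/Chop-/- library 2 and -0.34 without PiZ libraries 1 and 4. The ribosomal median was -0.19 without PiZ library 4, and the proteasome median -0.17 without PiZ libraries 1 and 4. No member of these 3 lists passed genome-wide; adjusted over the list alone, 0 ribosomal, 2 proteasome or heat shock and 1 synthetase gene did. Mars, the synthetase for methionine, was not on the list.

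Of 34 cell cycle genes 9 had enough counts to be tested, and as a list these were lower. Among them 2 of 9 fell, none rose and 7 were below 0, the same 2 falling when adjusted over the list alone. The median was -0.72 (camera adjusted p = 0.000168, and 0.244 with an estimated correlation). PiZ/Chop-/- library 2 scored -0.029, against -0.58 to -0.49 in the other libraries of its group. Plk1, a kinase of mitosis, fell from 8.38 ± 1.91 to 0.760 ± 0.633 CPM (SD, n = 4 each; log2 fold change -3.38, SE 0.57, adjusted p = 0.00575), and missed the threshold without PiZ libraries 1 and 4 (adjusted p = 0.0509). Birc5, survivin, fell (-2.56, SE 0.50, adjusted p = 0.0193), a call lost without PiZ library 2 or 3 (adjusted p = 0.0580 and 0.105) and without PiZ/Chop-/- library 1, 3 or 4 (0.0791, 0.0921 and 0.0637).

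Stellate cell, macrophage and lymphocyte lists were lower, while the lists of 4 other cell types did not pass. Of 20 stellate cell and matrix genes 19 were below 0 (median -0.49, adjusted p = 7.14e-05; adjusted p = 0.336 with an estimated correlation); none passed genome-wide and 2 did when adjusted over the list alone, and Col1a1, a chain of type I collagen, had -1.15 (adjusted p = 0.0788), past the threshold without PiZ library 4 (0.0345). Of 20 Kupffer cell and macrophage genes 17 were below 0 (median -0.32, adjusted p = 0.00324; adjusted p = 0.356 with an estimated correlation), with Ctss at -0.75 (adjusted p = 0.118) and Cd5l at -0.71 (0.179). Of 30 genes on the list of T, NK and B cells 6 had enough counts to be tested, and all 6 were below 0 (median -0.47, adjusted p = 0.00929; adjusted p = 0.336 with an estimated correlation), with H2-Ab1 at -0.54 (0.314) and H2-Eb1 at -0.65 (0.347); that list was lost without PiZ/Chop-/- library 2 (adjusted p = 0.0702) and without PiZ libraries 1 and 4 (0.0776). Of these 6, H2-Aa, H2-Ab1, H2-Eb1 and Cd74 act in MHC class II antigen presentation, which macrophages share, and Ptprc is a marker of all white blood cells, so the list does not tell lymphocytes from macrophages. No gene of the macrophage or lymphocyte list passed singly, genome-wide or adjusted over the list alone. Endothelial (median 0.21, adjusted p = 0.0718), cholangiocyte (-0.19, adjusted p = 0.311), red cell (0.36, adjusted p = 0.693) and neutrophil markers (0.35, adjusted p = 0.710) did not pass. Enough counts were found for 24 of 27 endothelial, 5 of 20 cholangiocyte, 7 of 19 red cell and 3 of 17 neutrophil genes. The cholangiocyte, red cell and neutrophil medians thus rest on few genes. The endothelial list passed without PiZ library 3 or 4 (adjusted p = 0.0454 and 0.0256). None of these 4 lists held a gene past the genome-wide threshold, and 1 neutrophil gene passed when adjusted over the list alone. Over the fits with libraries or genes left out, their medians ran from 0.10 to 0.25 (endothelial), -0.31 to 0.095 (cholangiocyte), -0.30 to 0.88 (red cell) and -1.65 to 0.71 (neutrophil). The cholangiocyte median was above 0 without PiZ library 1, the red cell median was -0.30 without PiZ/Chop-/- library 3, and the neutrophil median was -1.65 without PiZ/Chop-/- library 2.

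Acute-phase proteins were lower, 2 of 27 falling, none rising and 23 below 0 (median -0.28, adjusted p = 0.00349; adjusted p = 0.436 with an estimated correlation), the same 2 when adjusted over the list alone. Apcs, serum amyloid P, fell from 326 ± 122 to 107 ± 16.6 CPM (SD, n = 4 each; log2 fold change -1.61, adjusted p = 0.00327). Lcn2, lipocalin 2, fell (-2.30, adjusted p = 0.0113), a call lost without PiZ/Chop-/- library 1 (adjusted p = 0.0688) or 3 (0.0626). The acute-phase list missed the threshold without PiZ library 1 (median -0.10, adjusted p = 0.103), and its median was -0.13 without PiZ libraries 1 and 4. NRF2 targets were lower, with 1 of 23, Cbr3, past the genome-wide threshold and 3 when adjusted over the list alone (median -0.12, adjusted p = 0.0232; adjusted p = 0.323 with an estimated correlation), and this list missed the threshold without PiZ/Chop-/- library 1 (adjusted p = 0.0872). The NRF2 median was -0.23 without PiZ library 1 and -0.24 without PiZ/Chop-/- library 3.

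Lists of secreted hepatocyte proteins, fat synthesis, hepatocyte transcription factors and periportal genes were higher, while pericentral genes did not pass and acute-phase proteins were lower. Of 38 abundant secreted hepatocyte proteins 31 were above 0 (median 0.24, adjusted p = 0.000733; adjusted p = 0.323 with an estimated correlation), C9 alone passing, also when adjusted over the list alone. Of 25 genes of fatty acid and triglyceride synthesis 16 were above 0 (median 0.28, adjusted p = 0.00506; adjusted p = 0.381 with an estimated correlation), a list lost without PiZ/Chop-/- library 2 (median 0.093, adjusted p = 0.0934), with a median of 0.42 without PiZ libraries 1 and 4. Its 1 riser, also when adjusted over the list alone, was Mlxipl, the carbohydrate-responsive factor ChREBP (log2 fold change 1.10, adjusted p = 0.0394), whose groups overlapped and whose call was lost without PiZ library 1, 2 or 3 (adjusted p = 0.108, 0.115 and 0.103), without PiZ/Chop-/- library 1, 3 or 4 (0.113, 0.149 and 0.128) and with library size as the only scaling (0.0929). Of 24 hepatocyte transcription factors 18 were above 0 (median 0.18, adjusted p = 0.0358; adjusted p = 0.323 with an estimated correlation), a list lost without PiZ library 1 (adjusted p = 0.0896), without PiZ/Chop-/- library 3 (0.0687) and without PiZ libraries 1 and 4 (0.0824). Its median was 0.28 without PiZ/Chop-/- library 2. None of its members passed, genome-wide or adjusted over the list alone. Onecut1 had 2.23 (adjusted p = 0.185) and passed without PiZ library 2 (3.19, adjusted p = 4.79e-05), as it did with DESeq2 (0.0344) and limma-voom (0.0128), and Thrb had 0.68 (0.341). Of 24 periportal genes 14 were above 0 (median 0.061, adjusted p = 0.0440; adjusted p = 0.323 with an estimated correlation), a list lost without PiZ library 2, 3 or 4 (adjusted p = 0.111, 0.0928 and 0.0553) and without PiZ/Chop-/- library 2 (0.119). The periportal median was 0.23, 0.19 and 0.15 without PiZ library 1, 2 or 4, 0.10 without PiZ/Chop-/- library 1 and 0.28 without PiZ libraries 1 and 4. Pigr, the receptor that carries IgA into bile, rose (1.24, adjusted p = 0.0139). Its log2 fold change was 1.03 to 1.37 over the leave-one-out fits, and the call was lost without PiZ library 3 or PiZ/Chop-/- library 1 (adjusted p = 0.0634 each). In this list 2 members passed when adjusted over the list alone.

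Male-biased liver genes were higher: all 22 tested, Serpina1e among them, were above 0 (median 0.96, adjusted p = 2.61e-11; adjusted p = 0.338 with an estimated correlation), 1 past the genome-wide threshold, Hsd3b5, and 11 when adjusted over the list alone. The estimated correlation among members was 0.78. PiZ library 1 had the lowest score of the 8 (median of the members' centred log2 CPM), -2.48 against -0.21 to 1.43 in the others. The list's median log2 fold change was 0.65 without that library. Female-biased genes went both ways, with 1 of 19 lower and 1 higher (median -0.51, adjusted p = 0.0440; adjusted p = 0.501 with an estimated correlation), and 5 lower and 1 higher when adjusted over the list alone. Cyp3a44, a cytochrome P450, fell (-3.65, adjusted p = 0.00458) but missed the threshold without PiZ libraries 1 and 4 (0.0509), and Lifr, the receptor of leukaemia inhibitory factor, rose from 173 ± 33.8 to 431 ± 54.9 CPM (SD, n = 4 each; log2 fold change 1.32, adjusted p = 0.00230). The female-biased list was lost without PiZ library 1, 2 or 3 (adjusted p = 0.193, 0.0761 and 0.0565) and without PiZ/Chop-/- library 1 or 2 (0.233 and 0.148), and its median was 0.14 without PiZ library 1, -0.84 without PiZ/Chop-/- library 3 and -0.21 without PiZ libraries 1 and 4. Ddx3y, a gene of the Y chromosome, was present in all 8 libraries (105 ± 18.3 and 112 ± 17.5 CPM), and Xist had at most 3 counts in any.

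**Figure D3:**
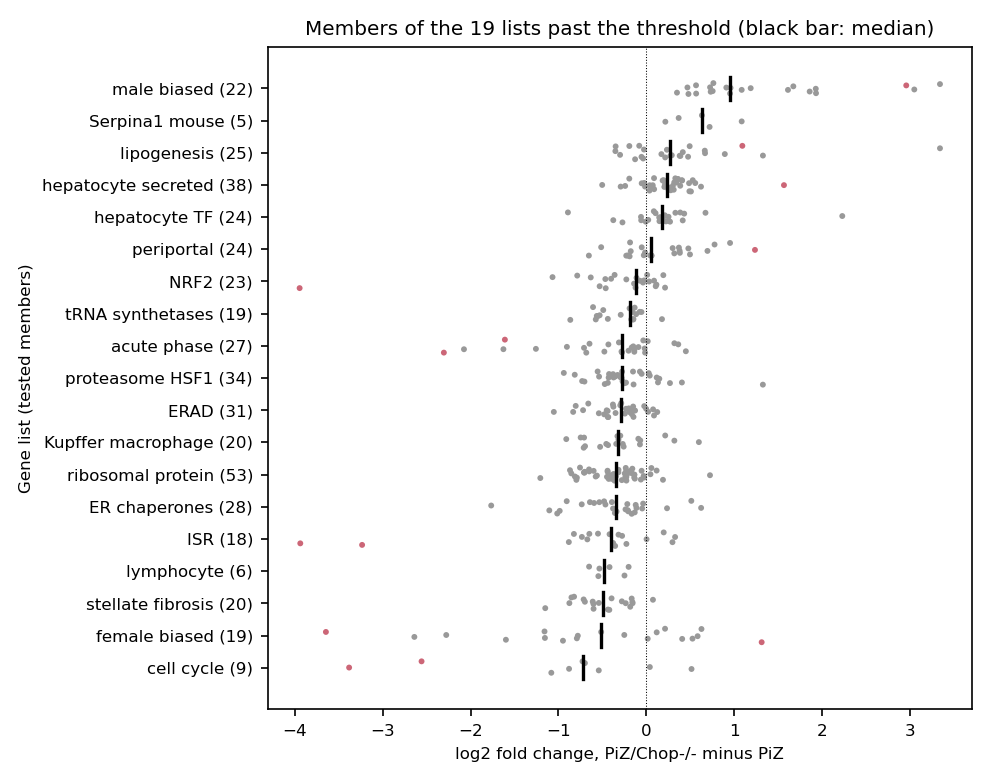
Log2 fold change, PiZ/Chop-/- minus PiZ (horizontal axis), of each tested member of the 19 gene lists past the camera threshold (vertical axis, number of members in brackets), with a black bar at the median and members past the genome-wide threshold in red. Medians ran from -0.72 (cell cycle) to 0.96 (male-biased), and most members were grey.

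In lists that did not pass as a whole, single enzymes and transporters changed. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 304 ± 82.0 to 87.9 ± 20.6 CPM (SD, n = 4 each; log2 fold change -1.79, SE 0.23, adjusted p = 0.000758); with Abcc4 it made 2 of 26 bile acid genes that fell, also adjusted over the list alone, while the list's median was 0.23 (adjusted p = 0.311). Among 20 pericentral genes (median -0.034, adjusted p = 0.693), Slc22a3, an organic cation transporter (-2.53, adjusted p = 0.000804), and Rhbg, an ammonium transporter (-1.66, adjusted p = 0.00353), fell. Gstm3 fell from 580 ± 237 to 145 ± 51.8 CPM (SD, n = 4 each; adjusted p = 0.0173, edgeR), while Ces1f rose (1.17, adjusted p = 0.0120). Adjusted over the list alone, 4 pericentral genes were higher and 3 lower. Among 34 drug-metabolising enzymes (median 0.10 and mean -0.0030, adjusted p = 0.693), Gstm2 and Gstm3, glutathione transferases, fell and Cyp2c38 rose, and 5 were higher and 5 lower when adjusted over the list alone. Direction by camera was up. Gstm2 (-0.94, adjusted p = 0.0155) was lost without PiZ library 2 or 3 (adjusted p = 0.0502 and 0.0649) and without PiZ/Chop-/- library 1, 3 or 4 (0.0734, 0.0697 and 0.0671). Gstm3 was lost without PiZ library 2 or 4 (0.0580 and 0.0643) or PiZ/Chop-/- library 3 (0.0831), and Ces1f without PiZ/Chop-/- library 1 (0.0569) or PiZ libraries 1 and 4 (0.0585). Ctsl, the lysosomal protease cathepsin L, fell (-1.36, adjusted p = 0.00458), the 1 genome-wide call among 37 autophagy and lysosome genes, of which 2 were lower when adjusted over the list alone, and whose median was 0.064 and mean -0.035 (camera direction down, adjusted p = 0.693). With libraries or genes left out the medians ran from 0.16 to 0.25 for bile acid genes, -0.092 to 0.20 for pericentral genes, 0.033 to 0.22 for drug-metabolising enzymes and -0.068 to 0.082 for autophagy and lysosome genes.

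The remaining lists held no gene past the genome-wide threshold and did not pass. Their medians were 0.17 for PPAR-alpha targets (adjusted p = 0.0612), 0.17 for interferon-stimulated genes (0.160), 0.024 for amino acid and urea enzymes (0.194), 0.71 for AP-1 and immediate early genes (0.248), 0.17 for mitochondrially encoded mRNAs (0.282), 0.31 for clock genes (0.311) and 0.16 for glucose metabolism (0.311). They were -0.085 for cholesterol synthesis (0.420), 0.0027 for NF-kB targets, whose mean was -0.26 (0.530), 0.015 for respiratory chain subunits (0.693) and -0.037 for apoptosis and p53 targets (0.743). These medians moved when libraries or genes were left out. They ran from -0.015 to 0.28 for PPAR-alpha targets, 0.066 to 0.33 for interferon genes, -0.035 to 0.18 for amino acid enzymes, 0.095 to 0.20 for mitochondrial mRNAs, 0.22 to 0.39 for clock genes and 0.0048 to 0.20 for glucose metabolism, which was lowest without PiZ libraries 1 and 4. They ran from -0.39 to 0.89 for AP-1 genes, -0.35 to 0.26 for cholesterol synthesis, -0.15 to 0.045 for NF-kB targets, -0.040 to 0.13 for the respiratory chain and -0.19 to 0.057 for apoptosis and p53 targets. Adjusted over the list alone, 1 interferon gene and 1 amino acid enzyme were higher, 1 NF-kB target was lower and none passed in the other lists of this paragraph. Some of these lists passed without 1 library. PPAR-alpha targets did so without PiZ library 2 or 3 (adjusted p = 0.0116 and 0.00720) or PiZ/Chop-/- library 2 (0.0289), and amino acid enzymes without PiZ library 1 (0.0262) or PiZ/Chop-/- library 3 (0.0413). Interferon genes passed without PiZ library 4 (0.0492), and AP-1 genes without PiZ/Chop-/- library 1 or 4 (0.0190 and 0.0359), although the AP-1 median was -0.39 without PiZ/Chop-/- library 2. Without that library cholesterol synthesis (median -0.35, adjusted p = 0.00201) and clock genes (0.39, adjusted p = 0.0244) passed. Without PiZ libraries 1 and 4 the respiratory chain (0.13, adjusted p = 0.0334), amino acid (0.18, adjusted p = 0.0311) and interferon lists (0.33, adjusted p = 0.0490) passed.

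Mars, the methionyl-tRNA synthetase gene beside Ddit3, fell from 57.4 ± 8.53 to 4.67 ± 1.14 CPM (SD, n = 4 each; log2 fold change -3.60, SE 0.26, adjusted p = 8.07e-07, edgeR; exact two-sided permutation p = 0.0286). It was chosen after its values were seen. Mars lies on the minus strand of chromosome 10 at 127296221 to 127311786 (mm10), and its 3' untranslated region overlaps that of Ddit3 over 68 bases, from 127296221 to 127296288. Whether the authors' counting used strand is not given in the sources used here, so which gene the reads there were assigned to is unknown. Within 10 Mb of Ddit3, 2 of 80 tested genes changed, Mars and Cd63, a tetraspanin of endosomes that fell from 311 ± 93.5 to 77.5 ± 20.9 CPM (adjusted p = 0.000383), against 86 of 8588 elsewhere. This share did not differ by Fisher's exact test (two-sided, odds ratio 2.53, 95% interval 0.297 to 9.75, p = 0.195), although it did without PiZ library 1 (odds ratio 4.33, Fisher's exact p = 0.0370). The odds ratio was 4.47 without PiZ library 3 and 4.88, 5.06 and 4.64 without PiZ/Chop-/- libraries 1, 3 and 4. Nnt, a gene with a deletion in some C57BL/6 substrains, stood at 14.7 ± 7.08 and 6.05 ± 2.63 CPM (log2 fold change -1.28, adjusted p = 0.215). PiZ libraries 2 to 4 had 16.7 to 19.9 CPM, above every PiZ/Chop-/- library (2.87 to 9.32 CPM). PiZ library 1, at 4.31 CPM (7 counts), lay within the PiZ/Chop-/- range. Whether the substrain differed between libraries was not tested.

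**Figure D4:**
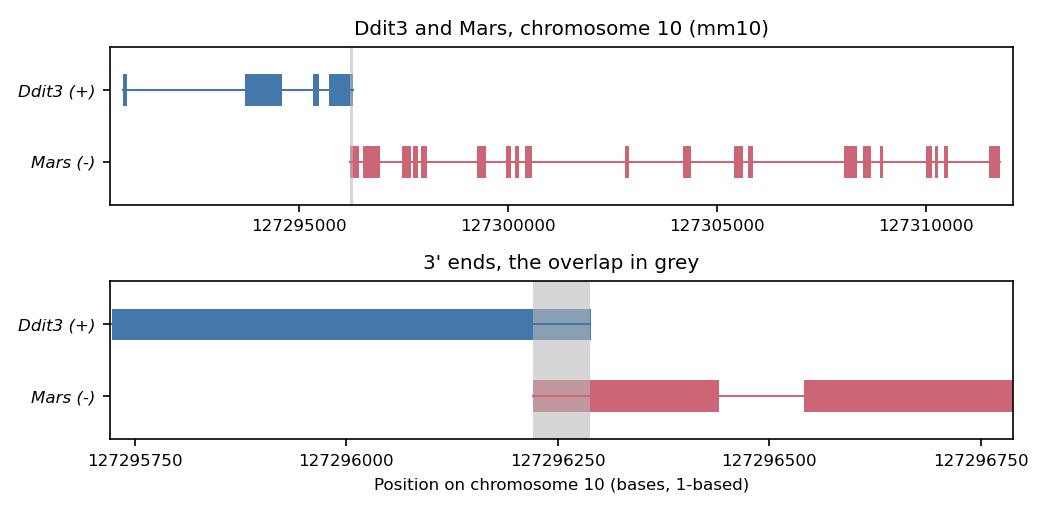
Exons (boxes) of Ddit3 and Mars on chromosome 10 of mm10, by position in bases, with both genes whole in the upper panel and their 3' ends enlarged in the lower panel. The grey band marks the 68 bases, 127296221 to 127296288, where the genes overlap on opposite strands.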

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

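The tests of the explanations for Mars, the male-biased genes and SERPINA1, and the comparison with other splits, were chosen only after the results were seen.

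A library was set apart in 9 of 138 groups of 4 values, because the gap from its value to the nearest other exceeded Dixon's 95% critical value for 4 samples. Chance alone does this in about 5% of groups. The groups were those of each named gene, of total counts and of the shares of Gm42418 and mitochondrial counts. PiZ/Chop-/- library 2 was the highest for Jun (162 CPM, others up to 40.7) and Atf4 (579 CPM, others up to 197) and the lowest for Rhbg (8.62 CPM, others from 19.9). PiZ library 4 was the highest for Psmb4 (515 CPM, others up to 303) and Serpina1c (4796 CPM, others up to 2252). PiZ library 2 was the highest for Onecut1 (73.4 CPM, others up to 20.9) and Ctss (64.1 CPM, others up to 52.7). PiZ library 1 was the lowest for Gstm2 (740 CPM, others from 883), and PiZ/Chop-/- library 3 the highest for Cbr3 (5.96 CPM, others up to 2.79).

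Chance as the source of the calls was tested with the 35 splits of the 8 libraries into 4 and 4. For genes changed, 1 of the 35, the real one, gave 89 calls or more, and the highest other split gave 2. The same held for genes lower, 60 against at most 2 in the larger direction of any other split (1 of 35), and for genes higher, 29 against at most 0 in the smaller direction (1 of 35). For the gene lists, 19 against at most 15, again 1 of 35 reached the real count. That share is the lowest these splits can give. The other splits mix the genotypes, so real differences add to their spread and they are not a clean null. Splits with 2 libraries of each group on either side hold no genotype contrast between their sides. They called at most 1 gene but still passed 2 to 10 lists. For the gene counts the real split stood far above every other. For the lists chance is not excluded: the margin was small, and with an estimated correlation 0 passed.

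The fall of Mars with Ddit3 has 3 explanations. A fall of all cytosolic aminoacyl-tRNA synthetases is argued against by the other 19, whose median log2 fold change was -0.19 (lowest -0.86; median -0.57 without PiZ/Chop-/- library 2) against -3.60 for Mars. Reads of Ddit3 counted as Mars may contribute, but the Mars to Ddit3 count ratio differed 3.15-fold among the 4 PiZ libraries, which sets single libraries against counting noise and does not decide. Whether the Mars 3' end was changed with the targeted allele or its flanking DNA is not known. Such a change could not be told apart from the effect of losing CHOP, since every PiZ/Chop-/- library carries the targeted allele. Of 58 other genes tested within 2 Mb, 1, Cd63, changed (Fisher's exact p = 0.444). An effect of CHOP on Mars stays open, untested.

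The rise of male-biased genes was set against 3 explanations. PiZ library 1 alone is argued against by the median of 0.65 without it (0.96 with it; adjusted p = 2.28e-07 with the preset and 0.425 with an estimated correlation). A female liver among the libraries is argued against by Ddx3y, at least 86.4 CPM in each of the 8, and Xist, at most 3 counts. A higher share of hepatocyte RNA is argued against as the whole source by the abundant secreted proteins, whose median was 0.24 and 90th percentile 0.52. The genotype stays open as a hypothesis, as do hormone differences, which were not measured, and differences in maturity, with which the falls of Afp (-4.09) and of cell cycle genes (median -0.72) would go.

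The fall of SERPINA1 was set against 3 explanations as well. Reads of the mouse paralogs counted as SERPINA1 are argued against by their summed CPM, which was 0.62 higher on the log2 scale in PiZ/Chop-/-, and a lower share of hepatocyte RNA by the secreted proteins, with a median of 0.24 and 31 of 38 above 0. Fewer transgene copies in the PiZ/Chop-/- mice cannot be told apart from an effect of CHOP, because copies were not measured. The log2 fold change differed by -0.23 (SE 0.22) from the -1 that 1 copy in place of 2 would give.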

How the results depend on the processing

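The SERPINA1 alternatives, the omission of PiZ libraries 1 and 4 together and that of Gm42418 with the mitochondrial genes were chosen after seeing the data. The fall of Ddit3 passed under every alternative run (-5.78 to -5.42). The 89 genes changed (29 higher, 60 lower) became 208 (94 and 114) with DESeq2 and 357 (175 and 182) with no filter, each of which held all 89. The DESeq2 fit also left out the expression filter of the main fit, and 19830 genes had a p-value against 8669. DESeq2 applies its own default filter on mean counts before adjustment, so fewer genes may have entered that step. The tool and the filter thus changed at once. The cause was not tested. They became 59 against a 1.2-fold minimum and 39 at an adjusted p of 0.01. Genes higher were 19 with library size only, which moved the median of all genes to -0.077, and 18 with limma-voom; the cause was not tested. Leaving out each library in turn gave 46 to 169 genes changed, 12 to 67 higher and 32 to 102 lower, with 1 library fewer per fit. In these fits SERPINA1 ranged from -1.38 to -1.07 and missed the threshold without PiZ/Chop-/- library 3 (it was -0.95 without PiZ libraries 1 and 4), and the odds ratio near Ddit3 ranged from 1.99 to 5.06. Of the 19 gene lists, 0 passed with an estimated correlation and 3 by fry. With a library left out 15 to 19 of the 19 passed, and 17 to 20 lists in all.

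The replicate numbers gave no clear sign of pairing. After each group's mean was subtracted from every gene, same-numbered libraries had correlations of 0.046, -0.051, 0.0061 and 0.049. With so few libraries these values do not settle whether the samples were paired. With the replicate block, 76 genes changed (28 higher, 48 lower), 61 of them among the 89, Ddit3 had -5.56, SERPINA1 -1.19, 19 lists passed and the odds ratio near Ddit3 was 2.99. Not every library correlated best with its own number.

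Directions turned for these genes and lists, none of them past the threshold with all 8 libraries; the cause was not tested. Over the leave-one-out fits Jun ran from -0.097 to 1.34, Rgs16 from -0.014 to 1.27 and Cebpb from -0.42 to 0.26. Cebpb was also -0.088 with library size only, -0.051 with limma-voom, -0.018 with the replicate block, -0.0080 with 1 surrogate variable and -0.055 without PiZ libraries 1 and 4, where Rgs16 was -0.14 and Ddx3y -0.11. The direction of the set test turned, with medians over the leave-one-out fits, for cholesterol synthesis (-0.35 to 0.18), drug metabolism (0.033 to 0.22), apoptosis and p53 (-0.13 to 0.039), the respiratory chain (-0.040 to 0.099), red cells (-0.30 to 0.84), neutrophils (-1.65 to 0.71) and AP-1 genes (-0.39 to 0.89). Without PiZ libraries 1 and 4 it turned for cholesterol synthesis (0.26), PPAR-alpha targets (-0.015), drug metabolism (0.069), clock genes (0.25) and pericentral genes (0.20). For the named genes past the threshold, Ddit3 and SERPINA1 aside, 651 single-gene alternatives kept the call and 63 lost it with the direction unchanged. The other called genes were not followed singly. Of all 89 calls, 43 to 82 were kept when 1 library was left out. With the depth, spread and number of these libraries, 34.2% of simulated 2-fold changes were recovered; depth alone was not varied.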

Other observations

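PiZ/Chop-/- library 2 differed from the other 3 in stress genes. Its score (median of the members' log2 CPM, each gene centred over the 8 libraries) was 0.16 for integrated stress response targets, against -0.58 to -0.19 in the other 3. For ER chaperones it was 0.22, against -0.37 to -0.30. For cholesterol synthesis it was 0.83, against -0.86 to 0.15. For AP-1 and immediate early genes it was 1.79, against -0.62 to -0.28.

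Human SERPINA1 made up 13.9% ± 5.31 of SERPINA1 plus mouse paralog CPM in PiZ and 4.08% ± 0.76 in PiZ/Chop-/- (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest possible). SERPINA1 was chosen after its values were seen and its own groups did not overlap, so the p of this share adds little. The summed paralog CPM was 9646 ± 3314 in PiZ and 14834 ± 2266 in PiZ/Chop-/- (exact permutation p = 0.0571).

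Gm42418, a gene model that collects ribosomal RNA reads, held 2.95% to 6.19% of counts in the PiZ libraries and 4.22% to 8.87% in the PiZ/Chop-/- libraries. PiZ library 4 had the lowest mean correlation with its own group (0.914, against 0.931 to 0.951) and the lowest position (-46.0) on the first principal component, which held 28.5% of the variance.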
